A study of Homo sapiens with 8 samples.

How the data were processed

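RNA from the EML4-ALK lung adenocarcinoma cell line H3122 and from its ceritinib-resistant derivatives H3122-LR2 and H3122-LR3 was measured on 8 single-colour expression arrays. Each line was measured untreated and after 6 h with 1000 nM ceritinib. Parental and LR2 cells were also measured after 6 h with 1000 nM crizotinib, and LR3 cells were not. Every condition had 1 array, so each line by agent condition is unreplicated. Per the labels' protocols, total RNA was isolated with an RNeasy kit, amplified with a 3' IVT kit and labelled with biotin. The deposited values are log2 probe set signals, and the submitters' processing notes name RMA as the method. The RMA software, its version and the arrays normalized together were not given in the sources used here. The number of arrays limits the precision of every value.

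The table held 49395 probe sets, of which 102 were AFFX controls. A probe set was used when the platform's probe table gave it 1 gene symbol, which left 44988 that were not controls. Each of the 18132 genes was represented by its probe set with the highest mean signal. A gene was tested when that signal exceeded 5.36, the 50th percentile of all probe set values, in at least 2 arrays. This left 10527 genes tested (58.1%) and 7605 too dim to test. Array medians lay between 5.31 and 5.36, except for 5.46 in the LR2 ceritinib array. GAPDH signal at the 3' end differed from that at the 5' end by -0.12 to -0.04, and ACTB signal by 0.09 to 0.26, in log2 units. No further normalization was applied. The probe table named no genome build, so no coordinates are given. The order of neighbouring genes was taken from a RefSeq table of assembly GCF_000001405.40 (GRCh38.p14).

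Line and agent comparisons used an additive limma model with terms for line and agent over all 8 arrays, with 3 residual degrees of freedom and empirical Bayes moderation (4.99 prior degrees of freedom). Inhibitor responses per line, and their differences between lines, used a model of 6 cells, line by inhibitor or none, in which crizotinib and ceritinib counted as 1 condition. That model had 2 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Values after ± are standard errors of limma, and n is the number of arrays matched by agent. Because LR3 had no crizotinib array, estimates of the additive model also drew on unmatched arrays and need not equal the mean of the matched pairs. The p-values of single genes measure only the spread between these arrays, mainly how a line difference varied across agents. They carry no information on separately grown cultures. Single-array differences are given as values without a test across arrays.

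The rule for named genes was fixed with the other choices before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes that moved in 1 direction in every matched pair of arrays. It added up to 4 called members of each gene list with the largest difference. Receptor, lineage and drug-resistance genes for line comparisons, and ERK, apoptosis and receptor genes for agent comparisons, were to be named whether called or not. The text names fewer genes than the rule allows, in the rule's order, and was shortened after the values were seen. This left out some uncalled genes of these groups, such as MET for LR3 against LR2, and inhibitor responses name DUSP6 and SPRY4 alone. Other probe sets of a gene were checked for their sign, and those of the opposite sign are given for called genes. Tested genes could lie below the floor of 5.36 on 1 side of a comparison, as MSN in parental cells and PAEP in LR2 did. Differences near background may be compressed, so the sizes and ranks of such genes are uncertain.

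The same plan fixed 39 gene lists. They covered FGF receptors and ligands, other receptor tyrosine kinases, EGFR, MET, AXL and IGF ligands, ERK pathway output, immediate early genes, FOXO targets and PI3K feedback, and the BCL2 family. Lineage and state lists covered epithelial, mesenchymal, lung lineage, squamous and basal, neuroendocrine and stem cell associated genes, and mucins with glandular secretory genes. Drug and stress lists covered drug efflux and uptake transporters, drug metabolism, NRF2 targets, cholesterol and SREBP genes, ATF4 and the unfolded protein response, heat shock, glycolysis and hypoxia, and lysosome and autophagy. Signalling lists covered interferon response, antigen presentation, NF-kB, STAT3, YAP and TEAD, TGF-beta, WNT, NOTCH, and RAS, SRC and MAPK pathway members. Growth lists covered G1/S, G2/M, cyclins with CDK inhibitors and p53 targets, MYC targets with ribosome biogenesis, and extracellular matrix, integrins and proteases. Markers of fibroblasts, leukocytes and endothelial cells served as lists of other cell types. A list was tested when at least 5 members were tested, which held for 38 lists.

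Lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. At the preset correlation camera compares a list's genes with the other genes. Its p-values take genes as the units and do not measure how a list's difference varied between arrays. No list in any comparison passed with an estimated correlation. That setting rests on the few residual degrees of freedom of these models, so it could hardly have called any list. Its adjusted p-values are given throughout but decide neither for nor against a list. How far correlation between genes weakens the calls at the preset correlation was therefore not settled. The fry test of limma, which asks whether a list's genes move on balance in 1 direction, was run on the same lists. It called 6 lists for LR2 against parental cells (camera 6, both 1), 12 for LR3 (camera 7, both 4), 5 for LR3 against LR2 (camera 4, both 2), and 1 each for crizotinib (camera 10) and ceritinib (camera 9), where no list was called by both. For ceritinib against crizotinib (camera 10) and for inhibitor responses fry of limma called 0. For single-array differences, list medians were ranked among the medians of 10000 random lists matched in size and signal. The overlap of LR2 and LR3 calls was set against 100 simulated experiments in which the 2 lines differed from parental cells only by noise and shared the parental arrays. Alternatives comprised no dim filter, a stricter filter, the mean of all probe sets, probe sets without cross-hybridization suffixes, centring, quantile normalization, trended and robust moderation, changed covariates, matched arrays alone, a 2-fold threshold, and leaving out each array. For lists, camera at the preset correlation was rerun only with the mean of all probe sets, without the dim filter and with each array left out. Windows of 20 neighbouring genes were compared with 200 random gene orders.

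The models were tested on simulated data with 10527 genes, 200 of them changed. All simulated genes changed 4-fold were recovered in each comparison simulated. Of genes changed 1.5-fold, 97.0% were recovered for LR2 against parental cells, 91.0% for crizotinib, 22.4% for the LR2 difference of inhibitor responses and 8.96% for the LR3 difference. Unchanged genes made up 8.76% of the calls for LR2 against parental cells 8.41% for LR3 and 10.6% for the parental inhibitor response, so the error rate exceeded the nominal 5% in these simulations. For the crizotinib and ceritinib comparisons the simulated agent effect was the same in every line, unlike in the measured arrays. These recovery rates did not carry over to the measured crizotinib comparison, where DUSP6, EGR1, CCND1 and ETV5 were not called. Nor did they carry over to the measured inhibitor responses. In parental cells DUSP6 had a log2 response of -4.75 and was not called by limma. The 68 genes at least 2-fold lower and the 46 higher with both agents were not called either. Missing calls for crizotinib and for inhibitor responses therefore do not show that 4-fold changes were absent. The work used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. Left out of the gene tests were 1832 probe sets with several gene symbols and 2569 without a listed symbol.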

Results

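The data comprised genome-wide RNA levels on 8 arrays from 3 human lung adenocarcinoma cell lines carrying the EML4-ALK fusion kinase. Parental H3122 cells and ceritinib-resistant H3122-LR2 cells were each measured untreated, with crizotinib and with ceritinib. Ceritinib-resistant H3122-LR3 cells were measured untreated and with ceritinib. Both agents inhibit the ALK kinase, and both were given at 1000 nM for 6 h. Values are log2 signals, differences are log2 differences, and each condition had 1 array without replicates.

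The comparison of LR2 with parental cells asked which genes differed in a ceritinib-resistant line across agents. AKR1C2, an aldo-keto reductase that acts on steroids and xenobiotics, was the gene with the largest rise, 2.67 ± 0.11 or 6.35-fold (higher in 3 of 3 matched arrays, adjusted p = 1.39e-05). S100A9, a calcium-binding protein of inflamed epithelium and myeloid cells, fell by 2.68 ± 0.14 or 6.39-fold (adjusted p = 3.95e-05). The receptor tyrosine kinase ALK itself rose by 1.21 ± 0.08 (adjusted p = 9.79e-05), and FGFR3, a fibroblast growth factor receptor, rose by 0.36 ± 0.07 (adjusted p = 0.0103). limma called 2369 of 10527 genes, 1350 higher and 1019 lower in LR2, and 113 of these differed at least 2-fold.

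Other large rises in LR2 were those of the intelectin ITLN1 (1.94 ± 0.10), the potassium channel subunit KCNS3 (1.90 ± 0.10), CALML5 (1.82 ± 0.10), the retinol dehydrogenase DHRS9 (1.72 ± 0.15), the secretoglobin SCGB3A1 (1.72 ± 0.08), AKR1C3 (1.68 ± 0.08) and the trypsinogen PRSS3 (1.59 ± 0.08). AKR1C1 rose by 1.58 ± 0.09. The AKR1C genes are close paralogs, so which of them each probe set read was not established, and 1 of the 2 AKR1C3 probe sets had the opposite sign. Other large falls were those of IGFL1 (-2.64 ± 0.17), PAEP (-2.53 ± 0.08), the adhesion molecule CADM1 (-2.45 ± 0.11), the GABA receptor subunit GABRB1 (-2.44 ± 0.07), SOBP (-2.17 ± 0.09), the membrane mucin MUC4 (-2.08 ± 0.11) and the matrix protein THBS1 (-1.92 ± 0.23). For CADM1 1 of 6 probe sets, and for SOBP 1 of 4, had the opposite sign. With the mean of all probe sets AKR1C3 in LR2 versus parental was 0.80 and MUC4 was -1.12. Each of these genes moved in 1 direction in 3 of 3 matched arrays.

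Among receptor genes, EPHB1, an ephrin receptor, rose by 1.34 ± 0.12 in LR2 (1 of its 6 probe sets had the opposite sign). The ligand FGF9 fell by 0.87 ± 0.08 (by 0.445 with the mean of its probe sets). FGFR1 (-0.10 ± 0.07, adjusted p = 0.345), FGFR4 (0.04 ± 0.07, adjusted p = 0.721) and EML4 (-0.12 ± 0.07, adjusted p = 0.281) were not called. ERBB2 (0.03 ± 0.07), ERBB3 (0.20 ± 0.09, adjusted p = 0.133), MET (0.06 ± 0.11) and IGF1R (-0.05 ± 0.13) were not called either. The cadherin CDH1 fell by 0.30 ± 0.07 (adjusted p = 0.0229), and the proliferation marker MKI67 differed by -0.11 ± 0.12 without a call. FGFR2, EGFR, KIT, AXL, ABCB1 and VIM were too dim to test.

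Extracellular matrix, integrin and protease genes were lower in LR2, with 11 of 24 tested members lower and 2 higher over all genes, and 13 lower and 2 higher adjusted over the list alone. The list median was -0.41, and camera gave an adjusted p = 1.5e-06 at the preset correlation and an adjusted p = 0.901 with an estimated correlation. With so few residual degrees of freedom the estimated setting could hardly have called any list, here or in the comparisons below. LAMB3, a laminin chain, fell by 1.61 ± 0.09, the protease inhibitor SERPINE2 by 1.60 ± 0.07 and the protease MMP10 by 1.57 ± 0.26. G1/S and DNA replication genes were higher, 13 of 39 over all genes and 13 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.000307, and adjusted p = 0.901 with an estimated correlation). CDC25A, a cell cycle phosphatase, rose by 0.83 ± 0.22, the cyclin CCNE2 by 0.71 ± 0.10, the replication helicase subunit MCM3 by 0.66 ± 0.07 and the transcription factor E2F1 by 0.56 ± 0.08.

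G2/M and mitosis genes were lower in LR2, 13 of 39 over all genes and 17 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 8.88e-05, and adjusted p = 0.901 with an estimated correlation). DLGAP5, a spindle protein, fell by 0.68 ± 0.09, and the centromeric histone CENPA by 0.62 ± 0.07. MYC targets and ribosome biogenesis genes had 12 of 38 members higher and 1 lower, against 17 higher and 2 lower adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.00525, and adjusted p = 0.901 with an estimated correlation). WDR43 rose by 0.81 ± 0.15, MYCL by 0.69 ± 0.17 and the RNA polymerase subunit POLR1C by 0.64 ± 0.12, while the polyamine enzyme ODC1 fell by 0.67 ± 0.12.

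FOXO targets and PI3K feedback genes had 8 of 23 members lower and 0 higher, against 8 lower and 1 higher adjusted over the list alone (median -0.12, camera adjusted p = 0.0253, and adjusted p = 0.901 with an estimated correlation). The ubiquitin ligase FBXO32 fell by 1.19 ± 0.17, TXNIP by 0.93 ± 0.16 and the cyclin CCNG2 by 0.89 ± 0.12 (1 of its 5 probe sets had the opposite sign). NOTCH signalling genes had 4 of 15 members lower, 4 also adjusted over the list alone (median -0.14, camera adjusted p = 0.0263, and adjusted p = 0.901 with an estimated correlation). LFNG, a modifier of NOTCH receptors, fell by 0.90 ± 0.08 and the coactivator MAML2 by 0.77 ± 0.11, with 1 of 2 MAML2 probe sets of the opposite sign. In lists that camera did not call, BPIFA1 fell by 1.74 ± 0.08, WFDC2 by 1.04 ± 0.08 and IFITM1 by 1.39 ± 0.09, while the transcription factor FOXA3 rose by 1.34 ± 0.10, the immunoproteasome subunit PSMB9 by 1.10 ± 0.10 (1 of its 3 probe sets had the opposite sign) and the proteoglycan LUM by 0.90 ± 0.16.

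The LR2 count was 1478 without the agent term, 1146 without the parental or without the LR2 crizotinib array, 1489 without the untreated parental array, 1350 without the LR2 ceritinib array and 1319 without the untreated LR2 array. With quantile normalization 1178 genes were higher and 1408 lower, so the larger share turned from higher to lower. In LR2 the CDH1 call was lost in 7 of 18 alternative fits, at an adjusted p of up to 0.111, and the FGFR3 call in 4, at up to 0.103, while ERBB3 was called in 3 and EML4 in 1. The CDC25A call was lost in 6, at up to 0.140, that of MMP10 in 4, ODC1 in 3 and MYCL in 2. The FOXO target list kept its camera call in 9 of 10 alternatives, with a highest adjusted p of 0.0817, and the other lists called in LR2 kept theirs in 10 of 10. Medians of single-array differences from parental cells, untreated, with crizotinib and with ceritinib, were uneven for MYC targets (0.10, 0.14 and 0.51), so that list's median rested mostly on the ceritinib arrays. They were -0.67, -0.63 and -0.26 for extracellular matrix, -0.10, -0.19 and -0.27 for G2/M, 0.16, 0.14 and 0.24 for G1/S, -0.30, -0.18 and -0.22 for FOXO targets, and -0.16, -0.20 and -0.07 for NOTCH genes.

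The comparison of LR3 with parental cells asked the same of the other resistant line. MSN, which links the actin cytoskeleton to the membrane, rose by 2.79 ± 0.11 or 6.90-fold (higher in 2 of 2 matched arrays, adjusted p = 1.31e-05). S100A9 fell by 4.57 ± 0.17 or 23.7-fold (adjusted p = 9.06e-06). FGFR3 rose by 1.14 ± 0.08 or 2.20-fold (adjusted p = 0.000182), and ALK by 0.84 ± 0.09 (adjusted p = 0.0012). limma called 2274 genes, 1003 higher and 1271 lower in LR3, and 162 of these differed at least 2-fold.

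LUM rose by 2.42 ± 0.19 in LR3, AKR1C2 by 2.29 ± 0.12, the interferon-induced IFI35 by 2.12 ± 0.16, the cancer-testis antigen MAGEC1 by 2.10 ± 0.16, the microvillus protein VIL1 by 1.94 ± 0.24, ANXA9 by 1.88 ± 0.09 and RFTN1 by 1.67 ± 0.11. LUM signal was 6.12 in both LR3 arrays and at most 4.03 in parental cells, below the floor of 5.36 for testing a gene. The airway secretory protein BPIFA1 fell by 3.48 ± 0.09, the proteoglycan GPC6 by 3.30 ± 0.12, IGFL1 by 2.99 ± 0.20, the pentraxin NPTX1 by 2.88 ± 0.24, CADM1 by 2.86 ± 0.12, SOBP by 2.62 ± 0.10 and MUC4 by 2.57 ± 0.13. With the mean of all probe sets NPTX1 fell by 1.58 and MUC4 by 1.39. For SOBP 2 of 4 probe sets had the opposite sign. Each of these genes moved in 1 direction in 2 of 2 matched arrays.

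Among receptor genes in LR3, the ephrin receptors EPHA3 and EPHB1 fell by 2.52 ± 0.15 and 1.21 ± 0.14, and the ligand FGF9 fell by 2.35 ± 0.10 (by 1.26 with the mean of its probe sets). FGFR1 (0.01 ± 0.08), FGFR4 (0.22 ± 0.09, adjusted p = 0.112) and EML4 (0.08 ± 0.09) were not called. ERBB2 (0.13 ± 0.08), ERBB3 (0.33 ± 0.10, adjusted p = 0.0511), MET (-0.02 ± 0.13), IGF1R (0.01 ± 0.15) and MKI67 (-0.32 ± 0.14, adjusted p = 0.151) were not called. CDH1 fell by 0.53 ± 0.09 (adjusted p = 0.005). The drug efflux pump ABCG2 rose by 1.60 ± 0.09 and the anion transporter SLCO4A1 by 1.06 ± 0.16, in a transporter list with 4 of 9 members higher, 4 also adjusted over the list alone, that camera did not call (adjusted p = 0.0549). The ligand BMP7 fell by 2.54 ± 0.12 and the receptor TGFBR2 by 1.14 ± 0.11, in a TGF-beta list with 6 of 19 members lower and 1 higher, 6 and 2 adjusted over the list alone, that was not called (adjusted p = 0.0549).

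The 2 FGFR3 probe sets differed in size. The brighter rose by 0.36 ± 0.08 in LR2 and by 1.14 ± 0.09 in LR3 when every probe set was fitted on its own. The fainter had a parental mean of 4.12, below the floor for testing genes. It rose by 3.09 ± 0.14 in LR3 (adjusted p = 2.53e-05) and differed by 0.13 ± 0.12 in LR2 (adjusted p = 0.472). Both ALK probe sets were higher, the fainter by 1.01 ± 0.07 in LR2 and 0.68 ± 0.08 in LR3, and the brighter by 1.21 ± 0.08 and 0.84 ± 0.10. Of 4 EML4 probe sets, 1 was called lower in LR2, at -0.39 ± 0.08 (adjusted p = 0.0112). These single fits were chosen after the FGFR3 probe sets were seen to differ.

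**Figure D1:**
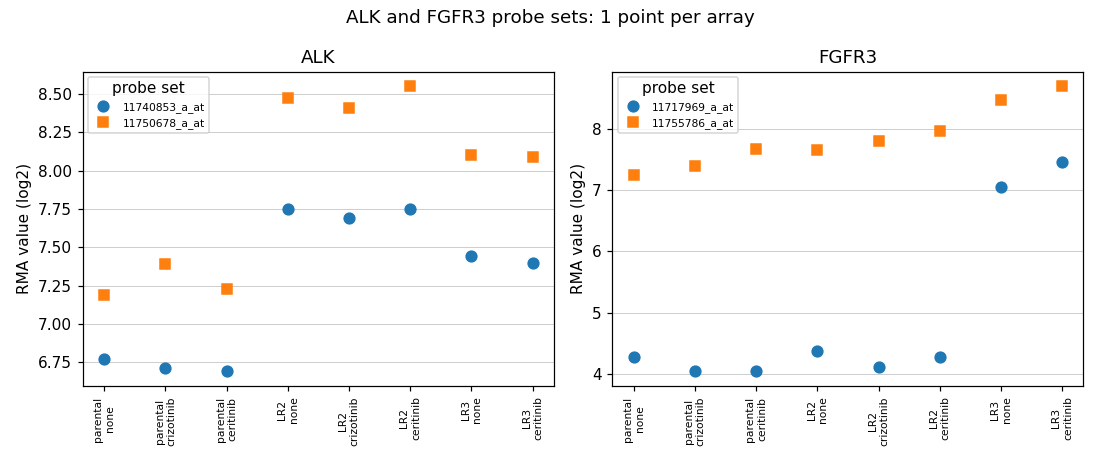
Log2 signal (vertical axis) of the 2 ALK probe sets and the 2 FGFR3 probe sets in each of the 8 arrays (horizontal axis), with 1 point per array and probe set. The brighter FGFR3 probe set lay at 8.48 and 8.70 in LR3 and between 7.25 and 7.68 in parental cells, and the brighter ALK probe set lay between 8.09 and 8.55 in the resistant lines and between 7.19 and 7.39 in parental cells.

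NRF2 target genes were higher in LR3, 9 of 23 higher and 2 lower over all genes, and 12 higher and 2 lower adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00145, and adjusted p = 0.676 with an estimated correlation). AKR1C3 rose by 1.18 ± 0.10 (0.41 with the mean of its probe sets, of which 1 of 2 had the opposite sign) and AKR1C1 by 1.04 ± 0.11, while the heme oxygenase HMOX1, another NRF2 target, fell by 1.84 ± 0.10. Antigen presentation genes had 10 of 21 members higher and 1 lower, against 12 higher and 1 lower adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.000689, and adjusted p = 0.696 with an estimated correlation). PSMB9 rose by 1.22 ± 0.11, PSMB8 by 0.93 ± 0.08 (1 of its 3 probe sets had the opposite sign) and HLA-C by 0.91 ± 0.08, and HLA-DMB fell by 1.16 ± 0.11. Of the 10 higher members, 8 lay in stretches of neighbouring genes that were shifted together in LR3. Glycolysis and hypoxia genes had 8 of 29 members higher and 1 lower, against 9 and 3 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.00813, and adjusted p = 0.838 with an estimated correlation). The phosphofructokinase genes PFKFB3 and PFKP rose by 0.90 ± 0.16 and 0.84 ± 0.12, and PFKFB3 by 0.36 without probe sets of cross-hybridization suffixes.

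G2/M and mitosis genes were lower in LR3, with 14 of 39 lower and 1 higher, the same counts adjusted over the list alone, and a median of -0.22 (camera adjusted p = 3.2e-05, and adjusted p = 0.8 with an estimated correlation). The list's difference lay mainly between the ceritinib arrays. The kinetochore gene NDC80 fell by 0.94 ± 0.10 and the checkpoint kinase TTK by 0.72 ± 0.10. FOXO targets and PI3K feedback genes had 8 of 23 members lower and 0 higher, against 11 lower and 2 higher adjusted over the list alone (median -0.42, camera adjusted p = 0.00727, and adjusted p = 0.676 with an estimated correlation). FBXO32 fell by 1.30 ± 0.20 and KLHL24 by 1.26 ± 0.24. Extracellular matrix genes had 9 of 24 members lower and 0 higher, against 13 lower and 1 higher adjusted over the list alone (median -0.33, camera adjusted p = 0.00441, and adjusted p = 0.8 with an estimated correlation). LAMB3 fell by 1.45 ± 0.11 and SERPINE2 by 1.38 ± 0.08.

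Squamous and basal genes had 5 of 12 members lower in LR3, 6 adjusted over the list alone (median -0.21, camera adjusted p = 0.00813, and adjusted p = 0.676 with an estimated correlation). SPRR1B, a cornified envelope protein, fell by 1.10 ± 0.18 and S100A2 by 1.03 ± 0.10. Of lung lineage genes, 6 of 18 were lower and 1 higher, 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0549). The surfactant proteins SFTPA1 and SFTPA2, which are close paralogs, fell by 1.81 ± 0.09 and 1.45 ± 0.08, and the alveolar gene HOPX rose by 1.52 ± 0.11.

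The LR3 count was 0 with matched arrays alone in pairs, which left 2 pairs, with 3092 genes at an unadjusted p under 0.05 in limma. It was 632 without the LR3 ceritinib array, 830 without the untreated LR3 array and 1283 without the untreated parental array, and centring each array turned the split to 1498 higher and 1223 lower. ERBB3 in LR3 was called in 6 of 18 alternative fits, with a lowest adjusted p of 0.00311. MKI67 in LR3 was called in 1 of 18. Every named call was lost with matched arrays alone. In total the KLHL24 call was lost in 4, those of FBXO32 and PFKFB3 in 3, that of CDH1 in 2, and those of ALK and FGFR3 in 1. The lists called in LR3 kept their camera calls in 10 of 10 alternatives, which did not include matched arrays alone. Medians of single-array differences from parental cells, untreated and with ceritinib, were 0.21 and 0.32 for NRF2 targets, 0.46 and 0.31 for antigen presentation, 0.15 and 0.27 for glycolysis, -0.07 and -0.34 for G2/M, -0.25 and -0.44 for FOXO targets, -0.475 and -0.215 for extracellular matrix, and -0.245 and -0.24 for squamous genes. The G2/M median therefore rested mostly on the ceritinib arrays, and G2/M genes rose less with ceritinib in LR3 than in parental cells.

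Calls in LR2 and LR3 overlapped in 857 genes of 1 direction, 411 higher and 446 lower in both, and 121 were opposite. Independent lists of these sizes would share 129 higher and 123 lower genes. Both lines were compared with the same parental arrays, and 100 simulated experiments with that sharing and no true difference called a mean of 0.02 genes in LR2 and 0 in LR3, so their 0 shared calls could not have come out otherwise. Across genes, which are not independent replicates, the line differences correlated with r = 0.473, against a simulated mean of 0.427 and maximum of 0.504, so r lay inside the simulated range. Their covariance was 0.0469, against a simulated mean of 0.00596 and maximum of 0.00819. The simulated noise was the spread between arrays, so it lacked any offset common to all parental arrays, which would add covariance. Part of the overlap may come from the shared controls. Single-array differences matched by agent were therefore also compared, a step chosen after the overlap was seen. The 2 pairs that shared a parental array correlated at 0.478 and 0.588 (covariance 0.0522 and 0.0842), with 45 and 90 genes at least 2-fold different in 1 direction and 2 opposite in each. The 4 pairs with different parental arrays, which also differed in agent, correlated at 0.271 to 0.377 (covariance 0.0338 to 0.0412), with 37 to 44 such genes in 1 direction and 4 to 8 opposite. All of these pairs still shared the parental line. Neither comparison can therefore separate changes common to the resistant lines from an offset common to the parental arrays. AKR1C2, AKR1C1, AKR1C3, LUM, ALK, FGFR3 and PSMB9 rose in both lines. S100A9, IGFL1, CADM1, SOBP, MUC4, BPIFA1, FGF9, LAMB3, SERPINE2, FBXO32 and CDH1 fell in both.

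The comparison of LR3 with LR2 tested the differences between the resistant lines. MSN was higher in LR3 by 3.38 ± 0.11 (adjusted p = 1.41e-05, 2 of 2 matched arrays), and BMP7 was lower at -2.91 ± 0.12 (adjusted p = 1.41e-05). FGFR3 was higher in LR3 by 0.77 ± 0.08 (adjusted p = 0.001), and ALK was lower at -0.37 ± 0.09 (adjusted p = 0.0295). FGFR1 (0.11 ± 0.08) and FGFR4 (0.18 ± 0.09) were not called. limma called 2064 genes, 767 higher and 1297 lower in LR3, and 165 of these differed at least 2-fold.

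Also higher in LR3 than in LR2 were IFI35 (2.38 ± 0.16), PAEP (2.34 ± 0.09), the mannosidase MAN1A1 (2.27 ± 0.10), ANXA9 (2.14 ± 0.09), the cyclooxygenase PTGS2 (2.12 ± 0.32), the chemokine CCL15 (1.95 ± 0.08) and the retinoic acid-binding CRABP2 (1.93 ± 0.08). Lower in LR3 were NPTX1 (-2.76 ± 0.24), the homeobox genes HOXB5 (-2.64 ± 0.12) and HOXB3 (-2.51 ± 0.16, but -1.01 with the mean of its probe sets and -0.83 without cross-hybridization suffixes), EPHB1 (-2.55 ± 0.14), EPHA3 (-2.37 ± 0.15), SCGB3A1 (-2.24 ± 0.09), the growth hormone receptor GHR (-2.17 ± 0.08) and FGF9 (-1.49 ± 0.10). Of drug transporters, SLCO4A1 was higher by 1.65 ± 0.16 and ABCG2 by 1.21 ± 0.09.

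Glycolysis and hypoxia genes were higher in LR3 than in LR2, with 11 of 29 higher and 1 lower, and 14 higher and 1 lower adjusted over the list alone (median 0.21, camera adjusted p = 0.000236, and adjusted p = 0.983 with an estimated correlation). PFKP was higher by 1.06 ± 0.12, the prolyl hydroxylase EGLN3 by 0.90 ± 0.21 and NDRG1 by 0.90 ± 0.09. Antigen presentation genes had 7 of 21 members higher, 7 also adjusted over the list alone (median 0.14, camera adjusted p = 0.0168, and adjusted p = 0.983 with an estimated correlation), with HLA-C at 0.64 ± 0.08. Lung lineage genes had 7 of 18 members lower and 1 higher, against 8 and 1 adjusted over the list alone (median -0.25, camera adjusted p = 0.0106, and adjusted p = 0.715 with an estimated correlation), with SFTPA1 at -1.67 ± 0.09 and LAMP3 at -1.39 ± 0.11. Squamous and basal genes had 6 of 12 members lower and 1 higher, the same adjusted over the list alone (median -0.58, camera adjusted p = 0.0106, and adjusted p = 0.715 with an estimated correlation), with SPRR1B at -1.39 ± 0.18 and the transcription factor PITX1 at -1.17 ± 0.09.

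The count for LR3 against LR2 was 544 with matched arrays alone, 710 without the LR3 ceritinib array, 907 without the untreated LR3 array, 1061 without the untreated LR2 array and 1293 without the LR2 ceritinib array. Centring gave 1290 higher and 1103 lower genes, and quantile normalization 1100 and 1217, so the split of directions depended on the scaling. The ALK call was lost in 6 of 18 alternative fits, at an adjusted p of up to 0.204, that of EGLN3 in 7, at up to 0.144, and those of HLA-C and PTGS2 in 1. The antigen presentation list kept its camera call in 8 of 10 alternatives, with a highest adjusted p of 0.113, and the other 3 lists called kept theirs in 10 of 10.

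Between untreated arrays alone, 138 genes differed at least 2-fold between LR2 and parental cells, 54 higher and 84 lower in LR2, with 1 array each and no test run. Between LR3 and parental cells 178 genes did, 49 higher and 129 lower. The ERK pathway output list, feedback regulators and targets of the MAP kinase ERK, had a median of -0.20 in untreated LR2 and -0.18 in untreated LR3 relative to parental cells, at percentiles 0.01 and 0.13 of random lists. In the model over all agents the same list had medians of 0.33 and 0.39, with 2 of 26 members higher in LR2, and 1 higher and 1 lower in LR3, against 0 in LR2 and 1 higher in LR3 adjusted over the list alone. These medians also drew on the ceritinib arrays, where the list fell far more in parental cells than in LR2 or LR3. They therefore do not show higher ERK output in untreated resistant cells. The list was not called (camera adjusted p = 0.369 and 0.0549).

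The comparison of crizotinib with no agent asked how the inhibitor changed parental and LR2 cells. The model's values also drew on the ceritinib and LR3 arrays, so they need not equal the means of the matched pairs. SPRY4, a feedback inhibitor of ERK signalling, fell by 3.25 ± 0.65 (lower in 2 of 2 matched arrays, adjusted p = 0.0416), and KLHL24 rose by 1.94 ± 0.24 (adjusted p = 0.0235). SPRY4 signal was 3.81 in both crizotinib arrays, below the floor of 5.36, so the size of its fall and its place among the falls are uncertain, and 1 of its 3 probe sets had the opposite sign. limma called 396 genes, 297 higher and 99 lower with crizotinib, and 56 of these changed at least 2-fold. Other large falls were those of PHLDA1 (-2.96 ± 0.64), the chromatin protein HMGA2 (-2.70 ± 0.55, with 3 of 6 probe sets of the opposite sign), the ephrin receptor EPHA2 (-2.46 ± 0.52), the kinase PLK2 (-2.31 ± 0.42), AMIGO2 (-2.01 ± 0.32, with 1 of 5 probe sets of the opposite sign), PHLDA2 (-1.95 ± 0.33) and TNFRSF12A (-1.88 ± 0.25). Other large rises were those of the AP-1 member FOSL2 (1.83 ± 0.22), PRR15L (1.78 ± 0.35), FBXO32 (1.70 ± 0.20), the glucose transporter SLC2A12 (1.62 ± 0.30), the xenobiotic-metabolizing CYP1A1 (1.60 ± 0.16), NPTX1 (1.52 ± 0.24) and CREBRF (1.44 ± 0.22).

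ERK pathway output genes fell with crizotinib, 6 of 26 over all genes and 22 adjusted over the list alone, with a median of -1.44 (camera adjusted p = 6.96e-15, and adjusted p = 0.653 with an estimated correlation). DUSP6, the ERK phosphatase, had a difference of -4.08 ± 1.06 (adjusted p = 0.0667), and EGR1 (-3.08 ± 0.79), CCND1 (-1.63 ± 0.36), ETV5 (-1.60 ± 0.37), MYC (-0.69 ± 0.21) and ETV4 (-0.37 ± 0.16) were not called either. With crizotinib DUSP6 signal went from 12.41 to 7.93 in parental cells and from 11.79 to 7.26 in LR2. CCND1 went from 12.19 to 10.5 and from 12.35 to 10.57, so both genes fell by similar amounts in the 2 lines. The model's error also includes how ceritinib responses varied between lines, so the missing calls do not speak against these falls. Immediate early genes had 2 of 21 members lower over all genes and 14 adjusted over the list alone (median -0.45, camera adjusted p = 1.63e-07, and adjusted p = 0.653 with an estimated correlation). G2/M and mitosis genes had 10 of 39 members higher over all genes and 23 adjusted over the list alone (median 0.32, camera adjusted p = 3.18e-13, and adjusted p = 0.653 with an estimated correlation), among them the phosphatase CDC25C (0.77 ± 0.08), ASPM (0.75 ± 0.08) and KIF20A (0.73 ± 0.12). MYC targets and ribosome biogenesis genes had 4 of 38 members lower and 1 higher, against 20 and 1 adjusted over the list alone (median -0.34, camera adjusted p = 5.04e-11, and adjusted p = 0.653 with an estimated correlation), among them BYSL (-0.94 ± 0.19), LYAR (-0.92 ± 0.17) and NOP16 (-0.89 ± 0.17, with 1 of 3 probe sets of the opposite sign).

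ATF4 and unfolded protein response genes had 5 of 31 members lower with crizotinib and 12 adjusted over the list alone (median -0.27, camera adjusted p = 7.47e-08, and adjusted p = 0.653 with an estimated correlation), with TRIB3 at -1.30 ± 0.20 and CHAC1 at -1.28 ± 0.23. FOXO targets and PI3K feedback genes had 10 of 23 members higher and 1 lower, against 12 and 4 adjusted over the list alone (median 0.38, camera adjusted p = 0.0029, and adjusted p = 0.653 with an estimated correlation), and the receptor ERBB3 rose by 0.55 ± 0.10. Drug metabolism genes had 5 of 14 members higher, 6 adjusted over the list alone (median 0.14, camera adjusted p = 0.00472, and adjusted p = 0.653 with an estimated correlation). The aryl hydrocarbon receptor targets AHRR, TIPARP and CYP1B1 rose by 0.94 ± 0.17, 0.70 ± 0.11 and 0.66 ± 0.10. Heat shock genes had 2 of 15 members lower, against 5 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0066, and adjusted p = 0.701 with an estimated correlation), with DNAJB1 at -0.82 ± 0.16. NF-kB genes had 1 of 15 members lower, 5 adjusted over the list alone (camera adjusted p = 0.0066, and adjusted p = 0.653 with an estimated correlation). Extracellular matrix genes had 0 of 24 members called by limma and 5 lower adjusted over the list alone (camera adjusted p = 0.0253, and adjusted p = 0.778 with an estimated correlation). In the BCL2 family the pro-apoptotic genes BMF (1.10 ± 0.13), BBC3 (0.70 ± 0.10) and BCL2L11 (0.69 ± 0.15, with 1 of 14 probe sets of the opposite sign) rose and PMAIP1 fell by 1.08 ± 0.19, with 5 of 18 members higher and 1 lower, 9 and 2 adjusted over the list alone, and that list was not called (camera adjusted p = 0.0885). FGFR3 differed by 0.13 ± 0.08 with crizotinib, without a call.

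The crizotinib count was 0 in limma without the parental crizotinib array, without the untreated parental array, without the LR2 crizotinib array, without the untreated LR2 array, or without a line term, with 1728, 1244, 1313, 1917 and 1197 genes at an unadjusted p under 0.05. It was 1529 without the parental ceritinib array (792 higher and 737 lower), 143 without the LR2 ceritinib array, 15 with matched arrays alone (2 higher and 13 lower, so the larger share turned from higher to lower), 151 without the dim filter, 258 with quantile normalization and 703 with trended and robust moderation. Each named call was lost in at least 5 alternative fits. The SPRY4 call was lost in 11 of 16, that of HMGA2 in 10 of 16, those of EPHA2, PRR15L and SLC2A12 in 11 of 17, and those of PHLDA1, BCL2L11 and ERBB3 in 10 of 17. Of the ERK genes not called with crizotinib, CCND1 was called in 7 of 17 alternative fits, EGR1 in 5, DUSP6 and ETV5 in 2, and MYC and ETV4 in 1. The extracellular matrix list kept its camera call in 8 of 10 alternatives, with a highest adjusted p of 0.140, and drug metabolism in 9, with one of 0.0583, while the other lists called kept theirs in 10 of 10.

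The comparison of ceritinib with no agent covered all 3 lines. DUSP6 had a difference of -1.81 ± 0.90 (lower in 3 of 3 matched arrays, adjusted p = 0.315), EGR1 of -1.97 ± 0.67 (adjusted p = 0.173) and SPRY4 of -1.16 ± 0.55 (adjusted p = 0.297). The DUSP6 difference was uneven over the lines, at -5.02 in parental cells, -0.28 in LR2 and -0.13 in LR3, and ranged from -0.20 without the parental ceritinib array to -2.74 without the LR2 ceritinib array. Over the alternatives EGR1 ranged from -2.945 to -0.86, SPRY4 from -1.74 to -0.18, CCND1 from -1.02 to -0.12 and ETV5 from -0.95 to -0.05, and each of these was smallest without the parental ceritinib array. CCND1 (-0.66 ± 0.31), ETV5 (-0.60 ± 0.32), MYC (-0.28 ± 0.18), ETV4 (-0.05 ± 0.14), BCL2L11 (0.41 ± 0.12), ERBB3 (0.42 ± 0.09) and FGFR3 (0.32 ± 0.07) were not called. limma called 0 genes, with 2017 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0638. Trended and robust moderation called 152 genes, and limma called 3 without the LR2 ceritinib array. ERBB3 was called in 1 of 17 alternative fits.

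With ceritinib, camera at the preset correlation called lower medians for ERK pathway output (-0.59, adjusted p = 9.32e-11), MYC targets (-0.19, adjusted p = 4.05e-10), ATF4 (-0.19, adjusted p = 4.05e-10), immediate early (-0.20, adjusted p = 1.18e-06), heat shock (-0.19, adjusted p = 1.43e-06) and cholesterol genes (-0.11, adjusted p = 2.73e-06). It called higher medians for G2/M (0.21, adjusted p = 2.53e-07) and FOXO targets (0.32, adjusted p = 0.0221). Each of these had an adjusted p = 0.676 with an estimated correlation. In single arrays the ERK median was -1.73 in parental cells, -0.10 in LR2 and -0.11 in LR3. NRF2 targets were called lower (adjusted p = 0.00794, and adjusted p = 0.676 with an estimated correlation) although their median was 0.01 and their mean -0.08. Adjusted over the list alone, 12 of 39 G2/M genes were higher, 12 of 23 FOXO genes were higher and 1 lower, 8 of 31 ATF4 genes were lower and 5 of 15 heat shock genes were lower. So were 3 of 38 MYC target genes, with 1 higher, 1 of 23 NRF2 genes, and 0 of the ERK, immediate early and cholesterol genes. The NRF2 list kept its camera call in 8 of 10 alternatives, with a highest adjusted p of 0.0600, and the other lists called kept theirs in 10 of 10.

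Crizotinib and ceritinib were compared at the same dose and time, with 2 arrays matched by line. The model's values also drew on the untreated and LR3 arrays, so they were not the means of the 2 pairs. The difference of ceritinib from crizotinib was 2.27 ± 1.06 for DUSP6 (95% interval -0.16 to 4.71, adjusted p = 0.791) and 2.09 ± 0.65 for SPRY4 (0.60 to 3.59, adjusted p = 0.771). The DUSP6 difference was -0.54 in the parental pair of arrays and 4.25 in the LR2 pair, and it ranged from 1.07 without the LR2 crizotinib array to 4.28 without the parental ceritinib array, where it was called. SPRY4 ranged from 1.19 to 3.31, EGR1 from 0.625 to 2.50, ETV5 from 0.48 to 1.69, CCND1 from 0.51 to 1.64, MYC from 0.18 to 0.77 and ETV4 from 0.145 to 0.56. Without that array SPRY4, EGR1, ETV5, CCND1, MYC and BCL2L11 were called as well. EGR1 (1.11 ± 0.79), ETV5 (0.996 ± 0.37), CCND1 (0.97 ± 0.36), MYC (0.41 ± 0.21), ETV4 (0.32 ± 0.16), FGFR3 (0.19 ± 0.08), ERBB3 (-0.13 ± 0.10) and BCL2L11 (-0.28 ± 0.15) were not called. limma called 0 genes, with 637 at an unadjusted p under 0.05, and 401 without the parental ceritinib array. The ERK pathway output list had a median of 0.86 (camera adjusted p = 4.41e-10, and adjusted p = 0.801 with an estimated correlation), with 0 of 26 members called over all genes and 0 adjusted over the list alone. Its median was -0.055 in the parental pair and 1.48 in the LR2 pair. It was among 10 of 38 lists that camera called at the preset correlation, and 0 were called with an estimated correlation. The ERK, G2/M and immediate early lists kept their calls in 10 of 10 alternatives, and the other 7 lost theirs in at least 1.

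Inhibitor responses were compared between the lines to ask whether resistant cells responded less. In parental cells the ERK pathway output list had medians of -1.63 with crizotinib and -1.73 with ceritinib, and 18 and 20 of 26 members were at least 2-fold lower. In LR2 cells the median was -1.43 with crizotinib, with 18 members at least 2-fold lower, and -0.10 with ceritinib, with 1. In LR3 cells it was -0.11 with ceritinib, with 0 members at least 2-fold lower. DUSP6 signal was 12.41 in untreated parental cells, 7.93 with crizotinib and 7.39 with ceritinib. In LR2 it was 11.79 untreated, 7.26 with crizotinib and 11.51 with ceritinib, and in LR3 12.17 untreated and 12.04 with ceritinib. Among 10000 random lists of the same size and signal, the ERK median ranked at percentile 0 in each of these arrays of parental and LR2 cells and at percentile 0.07 in LR3. With ceritinib the random lists had a median of 0.095 in LR2, where 20 of 26 members were lower, and of 0.015 in LR3, where 18 were lower. The list was therefore still lower than other genes with ceritinib in LR2 and LR3, by less than in parental cells. These ranks compare genes within 1 array each and are not a test across arrays.

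**Figure D2:**
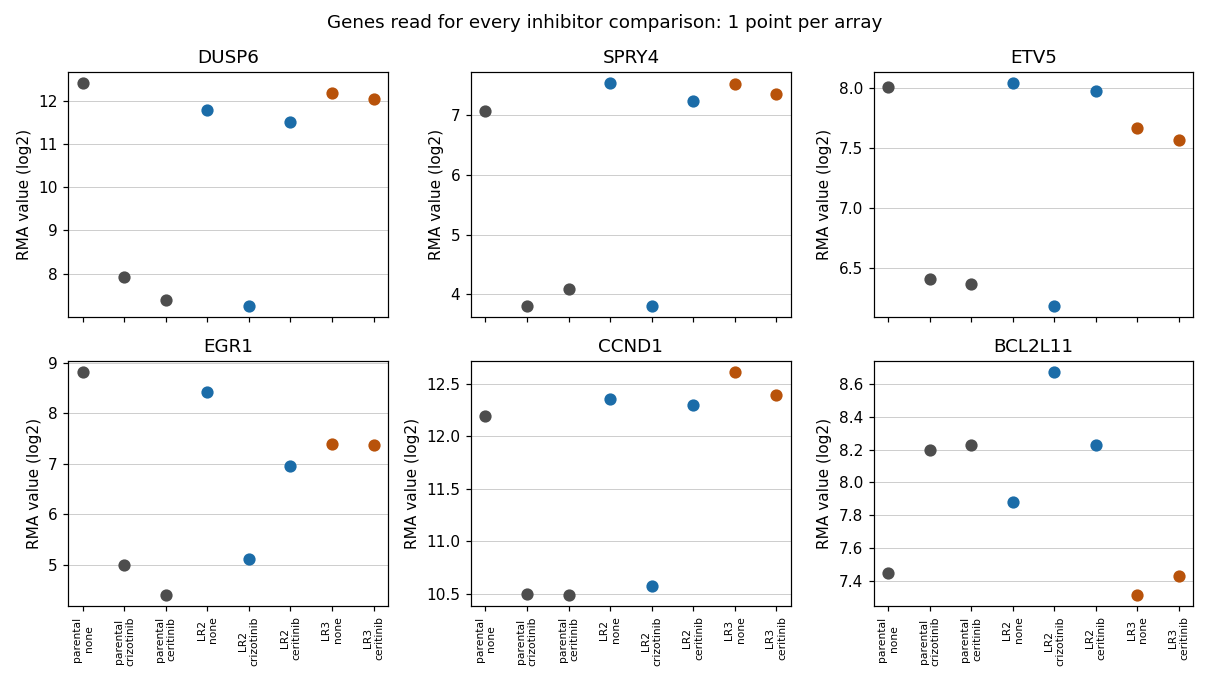
Log2 signal (vertical axes) of DUSP6, SPRY4, ETV5, EGR1, CCND1 and BCL2L11 in each of the 8 arrays (horizontal axis), with 1 point per array. DUSP6 lay at 7.26 in LR2 with crizotinib and at 11.51 with ceritinib, and SPRY4 at 3.81 and 7.23.

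Over all tested genes, 147 differed at least 2-fold from untreated in parental cells with crizotinib and 159 with ceritinib. In LR2 123 did with crizotinib and 3 with ceritinib, and in LR3 4 did with ceritinib. Of the 68 genes at least 2-fold lower with both agents in parental cells, 58 were at least 2-fold lower in LR2 with crizotinib, 1 with ceritinib and 0 in LR3 with ceritinib, with medians of -1.48, -0.27 and -0.13. The 46 genes at least 2-fold higher in parental cells had medians of 1.03 in LR2 with crizotinib, 0.44 in LR2 with ceritinib and 0.39 in LR3 with ceritinib. G2/M genes had medians of 0.41 and 0.35 in parental cells, 0.36 and 0.21 in LR2 with crizotinib and ceritinib, and 0.09 in LR3, each at percentile 100 of random lists. MYC target genes had medians of -0.33 and -0.39 in parental cells, -0.39 and -0.01 in LR2, and -0.19 in LR3. All genes had a median of 0.10 in LR2 with ceritinib, where random lists matched to the MYC list had a median of 0.085 and that list ranked at percentile 0, so relative to other genes it was lower there too.

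With both agents as 1 condition, DUSP6 had an inhibitor response of -4.75 ± 1.59 in parental cells (adjusted p = 0.229), -2.41 ± 1.59 in LR2 (adjusted p = 0.669) and -0.13 ± 1.84 in LR3 (adjusted p = 0.989). SPRY4 had -3.12 ± 1.28, -2.02 ± 1.28 and -0.17 ± 1.48, with signals of 3.81 and 4.08 below the floor in treated parental cells and of 3.81 in LR2 with crizotinib. limma called 0 genes in parental, LR2 and LR3 cells, with 1849, 1015 and 499 at an unadjusted p under 0.05. The difference of responses from parental cells was 2.35 ± 2.25 for DUSP6 and 1.10 ± 1.81 for SPRY4 in LR2 (adjusted p = 0.998 for both), and 4.62 ± 2.44 and 2.96 ± 1.95 in LR3 (adjusted p = 0.91 and 0.917). limma called 0 genes for both differences, with 251 for LR2 and 505 for LR3 at an unadjusted p under 0.05.

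The ERK pathway output list responded less in LR2 than in parental cells by a median of 0.87 (camera adjusted p = 8.09e-05, and adjusted p = 0.98 with an estimated correlation), and less in LR3 by 1.60 (camera adjusted p = 1.11e-12, and adjusted p = 0.984 with an estimated correlation), with 0 of 26 members called over all genes and 0 adjusted over the list alone. In single arrays the list's medians with crizotinib were -1.43 in LR2 and -1.63 in parental cells, so the LR2 difference lay mainly in its ceritinib array. Without that array it was 0.15 and was not called, with an adjusted p of 0.0838, the highest of 8 alternatives, and the call was kept in the other 7. Camera called 4 lists for the LR2 difference and 8 for the LR3 difference at the preset correlation, and 0 with an estimated correlation. Of these, 1 and 7 kept their calls in every alternative run. Fry, which does not compare the list with other genes, gave an adjusted p = 0.929 for LR2 and 0.912 for LR3. In LR2, DUSP6 differed by 4.25 between ceritinib and crizotinib, and with both agents as 1 condition that spread entered the error of its response. With the 2 parental inhibitor arrays as the only replicates, a model added after this was seen, limma called 0 genes in each contrast, with 1069 at an unadjusted p under 0.05 for the LR3 difference and 656 for the LR2 difference.

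Neighbouring genes were compared as windows of 20 tested genes in chromosome order. In LR2, 205 of 10082 windows had a median difference from parental cells beyond the largest of 200 random gene orders, 134 higher and 71 lower, in 16 separate stretches. In LR3, 370 windows did, 62 higher and 308 lower, in 15 stretches. In the parental inhibitor response 0 windows did. In LR2, the stretch from SESTD1 to PNKD held 90 genes with a median of 0.35, and that from PPM1A to CPSF2 114 genes with a median of -0.29. In LR3, the stretch from PRRT3 to PLXNB1 held 131 genes with a median of -0.41, that from CLNS1A to IFT46 111 genes with a median of -0.36, and that from TRIM27 to PPT2 60 genes with a median of 0.38.

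**Figure D3:**
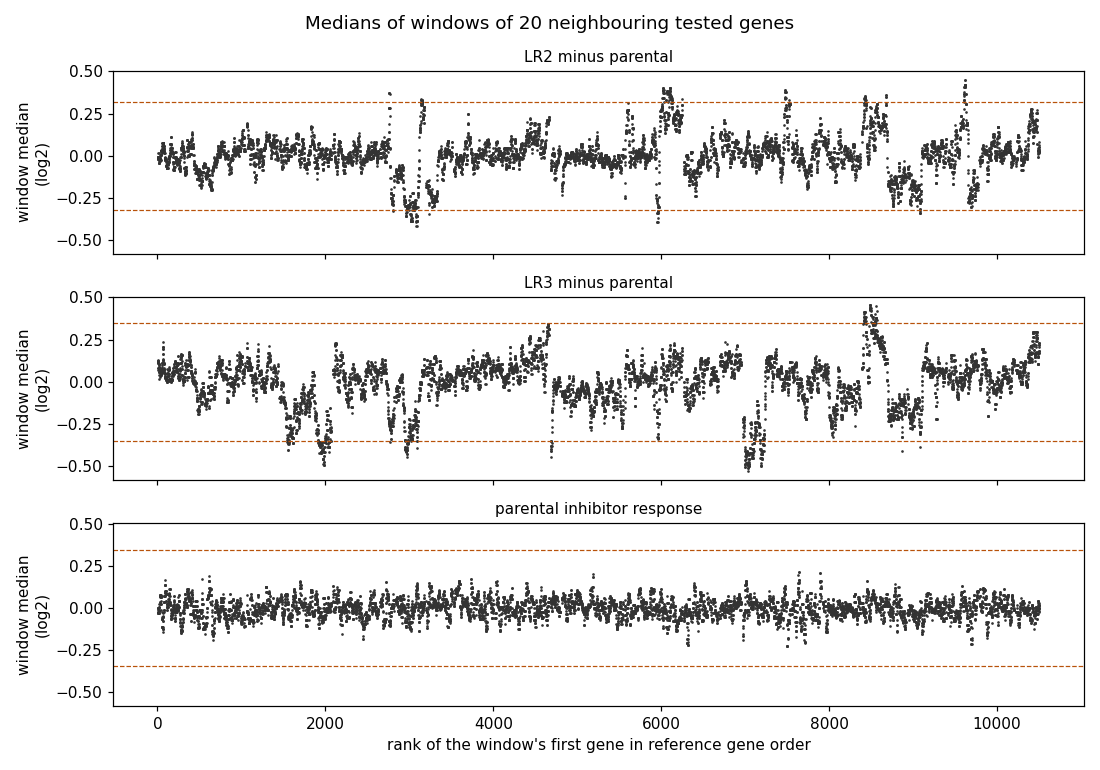
Median log2 difference (vertical axes) of windows of 20 neighbouring tested genes, with 1 point per window at the rank of its opening gene in reference gene order (horizontal axis), for LR2 minus parental, LR3 minus parental and the parental inhibitor response. Dashed lines mark the largest window of 200 random gene orders, 0.32 for LR2, 0.351 for LR3 and 0.343 for the inhibitor response, and 205, 370 and 0 windows lay beyond them.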

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

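The tests on undosed cells, on an array-wide shift and on a constant signal in the FGFR3 probe sets were chosen only after the results they address were seen. The tests on swapped arrays, on a gain around ALK and on other splits of the arrays were not.

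ERK pathway output genes had a median of -1.43 in LR2 with crizotinib and of -0.10 with ceritinib. Undosed cells in the ceritinib array were argued against, since the 46 genes at least 2-fold higher with both agents in parental cells had a median 0.34 above that of all genes there (bootstrap 0.24 to 0.43), with 46 of 46 above it. The higher overall level of that array was argued against too, since after subtracting the all-gene median of 0.09 the list still differed by 1.39 between ceritinib and crizotinib, with 26 of 26 members above that median. An exchange of the LR2 crizotinib and ceritinib arrays could not be excluded. The test used 6716 genes with a small mean response in parental cells and a small response of LR2 cells to crizotinib. Across them the agent differences of parental and LR2 cells correlated at only 0.0331, between the bounds set for and against an exchange. The LR2 response to ceritinib was not limited, so the choice of genes used 1 of the 2 arrays in question. A weaker effect of ceritinib than of crizotinib on ERK output genes in this ceritinib-resistant line may therefore hold. It rests on 1 array per agent and on the absence of that exchange. ALK activity was not measured, so whether the agents differed in their action on ALK or elsewhere cannot be told.

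ALK signal was higher in LR2 and LR3 in both probe sets. An even gain of the segment on both sides of ALK as the whole source was argued against. The 20 tested genes nearest to ALK had a median LR2 difference of 0.12 against 1.21 for ALK, with quartiles of -0.07 and 0.34. In LR3 their median was 0.10. In LR2 7 of the 20 neighbours were called higher, all on the same side of ALK, among them WDR43 at 0.81 and CLIP4 at 0.74. YPEL5, on the other side, was called lower at -0.42. A median over both sides cannot exclude a gain on 1 side, so such a gain stays open. A smaller gain could also add to the signal, and a gain of ALK alone was not tested. More transcription of ALK or of its fusion may also contribute, which probe sets for the whole gene cannot separate.

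The fainter FGFR3 probe set rose by 3.09 in LR3 and differed by 0.13 in LR2, where the brighter one rose by 0.36. A constant unspecific signal in the brighter probe set was argued against only under an assumption. If the fainter one's gain kept the ratio to the brighter one seen in LR3, its log2 change in LR2 would be 1.43. It was 0.16 over the untreated and ceritinib arrays used here. Signal lost near background would break that assumption. TACC3, an adjacent gene noticed after its values were seen, rose by 1.24 in LR3 and differed by 0.17 in LR2, while the 20 tested genes nearest to FGFR3 had a median of 0.00792 in LR3. Transcripts of FGFR3 that the probe sets read differently, with a difference in their use between LR2 and LR3, may account for the probe sets, and loss of small differences near the background of the fainter one, at a parental mean of 4.12, was not tested. A change in LR3 that covers FGFR3 and TACC3 alone also stays open.

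Among the 10 splits of the 6 parental and LR2 arrays into groups of 3, 1 gave as many called genes as the real split (2369), and the highest other gave 13. For ceritinib, 10 of 10 splits gave at least the real count of 0, as any split must, and the highest other, which set the LR3 arrays and the parental ceritinib array against the rest, gave 258 and followed the structure of the lines. In both cases the splits are too few for a share under 0.05.

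ETV4, an ERK target, stood apart because its inhibitor response was 0.34 in LR3 while both parental responses were lower, with a mean of -0.37, and the difference between the lines was not called by limma (adjusted p = 0.91). Probe sets with several gene symbols or none, which no comparison of genes used, held 520 calls among 2018 tested for LR2 against parental cells. This was 25.8%, against 22.5% of genes. The same probe sets held 441 calls for LR3 against parental cells, 21.9% against 21.6% of genes, so both shares were close to those of the genes.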

How the results depend on the processing

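The single probe set fits, the model with the parental inhibitor arrays as the only replicates, and the alternatives for the single-array ERK medians were chosen after the results were seen. Among named genes called, all 46 for LR2 against parental cells, 46 for LR3 against parental cells, 29 for LR3 against LR2 and 33 for crizotinib kept their direction under every alternative run. Of these, 32, 0, 25 and 0 stayed called under all of them. The causes of the changes below were not tested, except that fewer arrays leave fewer residual degrees of freedom. Fits that leave a condition without its array assume that the remaining arrays vary alike. The floor left out 7605 genes by choice and lay well above background. Without it these genes were tested too, and 1995 genes were called for LR2, 1789 for LR3 and 1750 for LR3 against LR2.

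For LR2 versus parental, the count of 2369 was 1478 without the agent term, 113 at 2-fold, and 1146 to 2116 when single arrays were left out (1146 without the parental or the LR2 crizotinib array, 1489 without untreated parental, 1350 without LR2 ceritinib, 1319 without untreated LR2). Quantile normalization gave 1178 higher and 1408 lower. For LR3 versus parental, the count of 2274 was 0 with matched arrays alone in pairs (limma, 3092 at an unadjusted p under 0.05), 162 at 2-fold, and 632 to 2311 with single arrays left out (632 without LR3 ceritinib, 830 without untreated LR3, 1283 without untreated parental). Centring gave 1498 higher and 1223 lower. For LR3 versus LR2, the count of 2064 was 544 with matched arrays alone, 165 at 2-fold, and 710 to 2630 with single arrays left out (710 without LR3 ceritinib, 907 without untreated LR3, 1061 without untreated LR2, 1293 without LR2 ceritinib). Centring gave 1290 higher and 1103 lower, and quantile normalization 1100 and 1217.

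For ceritinib versus none, the count of 0 in limma (2017 at an unadjusted p under 0.05) was 152 with trended and robust moderation, and 0 to 3 with single arrays left out (3 without LR2 ceritinib). For crizotinib versus none, the count of 396 was 151 without the dim filter, 258 with quantile normalization, 703 with trended and robust moderation, 0 without a line term (limma, 1197 at an unadjusted p under 0.05), 15 with matched arrays alone and 56 at 2-fold. With single arrays left out it was 0 to 1529 (0 without parental crizotinib, untreated parental, LR2 crizotinib or untreated LR2, with 1728, 1244, 1313 and 1917 at an unadjusted p under 0.05, 1529 without parental ceritinib, 143 without LR2 ceritinib). For ceritinib versus crizotinib it was 0 to 401 (401 without parental ceritinib).

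For the inhibitor response in parental cells, the count of 0 in limma (1849 at an unadjusted p under 0.05) was 2 with trended and robust moderation. Ceritinib arrays alone, at 2-fold and without a test, gave 159 genes in parental cells, 3 in LR2 and 4 in LR3, and 95 for the LR2 and 110 for the LR3 difference from parental cells. The model with the parental inhibitor arrays as the only replicates called 0 genes in limma (2401 at an unadjusted p under 0.05 in parental cells, lowest adjusted p 0.155). With 1 residual degree of freedom it could hardly have called any. Of single-array differences at 2-fold, the 138 of untreated LR2 were 211 between ceritinib arrays and 84 with the mean of all probe sets, and the 178 of untreated LR3 were 113 with that mean. The 857 genes shared by LR2 and LR3 were 40 at 2-fold.

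Of the genes named, a list shortened after values were seen, those that turned direction had not been called. In LR2 versus parental, with single arrays left out, FGFR4 ranged from -0.00267 to 0.096, MET from -0.10 to 0.17 and IGF1R from -0.16 to 0.10. ERBB2 in LR2 versus parental was -0.0787 with the mean of all probe sets and -0.0210 with quantile normalization. ERBB2 in LR3 versus parental was -0.0433 with that mean, and FGFR1 in LR3 versus parental ranged from -0.0417 to 0.0633. MET in LR3 versus parental was 0.0751 with that mean, 0.00917 with centring, 0.09 without the agent term, 0.05 with both agents as 1, 0.01 in matched pairs and -0.22 to 0.11 with single arrays left out. IGF1R in LR3 versus parental was -0.00677 with quantile normalization, -0.0767 without the agent term, -0.0258 with both agents as 1, -0.045 in matched pairs and -0.29 to 0.31 with single arrays left out. FGFR3 with crizotinib was -0.0108 with that mean and -0.19 without a line term. With ceritinib and single arrays left out, ETV4 ranged from -0.24 to 0.13 and MYC from -0.47 to 0.006. SPRY4 in the LR2 difference of responses ranged from -0.60 to 2.82 with single arrays left out, and was -0.60 without LR2 ceritinib.

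Sizes of called genes that moved more than 1.5-fold did so mostly with the mean of all probe sets. In LR2 versus parental, that mean gave 0.80 for AKR1C3, -0.55 for CCNG2, -0.445 for FGF9, -0.365 for MAML2 and -1.12 for MUC4, and CDC25A was 0.46 and MYCL 0.44 without parental ceritinib. In LR3 versus parental, it gave 0.97 for ABCG2, 1.41 for AKR1C2, 0.41 for AKR1C3, -1.61 for BMP7, -1.26 for FGF9, 2.11 for FGFR3, 0.51 for HLA-C, -1.39 for MUC4, -1.58 for NPTX1, 0.70 for SLCO4A1 and -0.72 for TGFBR2, and PFKFB3 was 0.36 without suffixed probe sets. In LR3 versus LR2, it gave 0.78 for ABCG2, -0.81 for FGF9, 1.86 for FGFR3, 0.37 for HLA-C, -1.01 for HOXB3, -1.48 for NPTX1 and 1.03 for SLCO4A1. With crizotinib, it gave 0.50 for AHRR, 0.415 for BBC3, 0.34 for BCL2L11, 0.67 for BMF and 0.83 for NPTX1 (2.46 without a line term), and ERBB3 was 0.35 without suffixed probe sets. In the LR2 difference of responses DUSP6 ranged from 0.22 to 4.47.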

Other observations

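HOXB genes, patterning factors that lie side by side in 1 cluster, were noticed among the largest differences between LR3 and LR2, and those named here beyond HOXB3 and HOXB5 were chosen after their values were seen. HOXB5 signal was 7.17 to 7.30 in parental cells, 7.86 to 8.38 in LR2 and 5.41 to 5.46 in LR3. HOXB3 was 1.01 ± 0.14 higher in LR2 than in parental cells and differed by -1.50 ± 0.16 in LR3, and its LR3 difference from LR2 was smaller with other probe sets (-0.83 to -1.01). HOXB6 was 0.90 ± 0.10 higher in LR2 and differed by -0.74 ± 0.12 in LR3. HOXB7 differed by 0.05 ± 0.07 in LR2, without a call, and by -0.32 ± 0.08 in LR3.

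The lists not yet described were called by camera in neither resistant line. Counts are of members higher and lower over all genes, with those adjusted over the list alone in parentheses, in LR2 and then in LR3. Of 8 FGF receptors and ligands 1 and 1 (1 and 1), then 1 and 1 (1 and 1) passed, of 24 other receptor tyrosine kinases 6 and 2 (6 and 2), then 4 and 4 (5 and 5), of 9 ligands of other receptors 1 and 2 (3 and 3), then 1 and 3 (1 and 3), and of 18 BCL2 family genes 4 and 2 (4 and 2), then 3 and 4 (3 and 5). Of 34 epithelial genes 5 and 4 (5 and 5), then 4 and 5 (6 and 5) passed, of 8 mesenchymal genes 1 and 3 (2 and 4), then 1 and 3 (1 and 4), of 10 neuroendocrine genes 1 and 2 (1 and 2), then 1 and 1 (1 and 1), and of 10 stem cell associated genes 2 and 1 (2 and 1), then 0 and 4 (0 and 5). Of 9 drug transporters 3 and 1 (5 and 1), then 4 and 0 (4 and 0) passed, of 27 cholesterol genes 9 and 2 (11 and 3), then 6 and 3 (6 and 3), of 21 interferon response genes 8 and 3 (8 and 4), then 8 and 2 (9 and 3), and of 31 lysosome and autophagy genes 2 and 5 (2 and 5), then 5 and 4 (5 and 6). Of 17 STAT3 genes 3 and 4 (6 and 5), then 2 and 4 (2 and 4) passed, of 16 YAP and TEAD targets 2 and 4 (2 and 4), then 1 and 7 (4 and 7), of 19 TGF-beta genes 3 and 4 (3 and 5), then 1 and 6 (2 and 6), of 15 WNT genes 4 and 2 (4 and 2), then 1 and 3 (1 and 3), and of 26 RAS, SRC and MAPK pathway genes 2 and 3 (1 and 3), then 4 and 4 (4 and 4). Of 25 cyclin, CDK inhibitor and p53 target genes 2 and 3 (1 and 2), then 3 and 6 (3 and 7) passed, of 19 mucin and secretory genes 5 and 6 (6 and 6), then 6 and 7 (6 and 7), and of 6 endothelial markers 0 and 2 (0 and 2), then 0 and 1 (0 and 1). Of 5 leukocyte markers limma called 0 in either line, and LUM was the 1 fibroblast marker bright enough to test.

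Medians, means and the direction of camera differed in sign for some uncalled lists. In LR2 these included epithelial genes (median 0.05, mean -0.01), mucins (0.08 and -0.12), STAT3 genes (0.13 and -0.10), WNT genes (0.01 and -0.05), FGF receptors and ligands (0.01 and -0.02), and squamous genes (-0.01 and 0.12). In LR3 they included ligands of other receptors (median 0.10, mean -0.25), mucins (0.03 and -0.26), NF-kB genes (-0.06 and 0.15), ATF4 genes (0.03 and -0.05), drug metabolism (0.01 and -0.13) and FGF receptors and ligands (0.03 and -0.12, called in neither direction).

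Neighbouring genes that shift together may reflect copy number differences between the lines. The test was set before its result was seen, and 575 windows of 20 neighbouring genes lay beyond the largest window of 200 random gene orders, 205 in LR2 and 370 in LR3. The same windows gave 0 for the inhibitor response of parental cells, which would share any grouping of co-expressed neighbours that responds to the agents. Of the antigen presentation list in LR3, 15 tested members lay inside the stretches with a median of 0.33 and 8 higher, and 6 lay outside with a median of 0.24 and 2 higher. The stretches were chosen by the same differences, so these values describe location only. No DNA was measured, so co-regulated gene neighbourhoods that differ between the lines stay open.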
